A study of Mus musculus with 6 samples.

How the data were processed

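The data were RNA sequencing profiles of wild-type mouse embryonic stem cells (ESCs) and epiblast-like cells (EpiLCs), 3 libraries of each. Per the labels' protocols, RNA was isolated with a combined DNA and RNA kit, poly(A) RNA was selected and fragmented, cDNA was primed with random and oligo(dT) primers, and the libraries kept strand information. The authors deposited 1 table of TPM values (an abundance estimate scaled for transcript length and library size), with 1 column per library and 78298 genes. FastQC, Trim Galore, STAR and Salmon and the mm39/GRCm39 genome build are named per the submitters' processing notes, without versions, annotation release or the role of each tool. How transcripts were summed to genes is not given in the sources used here. Column names carry a tag reading 0uM that no label explains. All 6 value columns matched 1 sample each by group and replicate number.

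Each column summed to 1000000 TPM. TPM keeps no depth, so read counts and counting intervals could not be given, and a count model was not used. Since TPM are shares of a library, a change in a few abundant genes shifts all others. Of the 78298 genes, 41623 were at 0 in all libraries. No pair of libraries within a group shared more than 0.003% identical nonzero values, so none was treated as a duplicate. Pearson correlations of log2(TPM + 1) were 0.988 to 0.991 within groups and 0.899 to 0.906 between groups, across genes, which are not independent replicates.

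Values were transformed as log2(TPM + 1), and genes with a mean TPM of at least 1 over the 6 libraries were tested (14036 genes). EpiLCs were compared with ESCs with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of adjusted p 0.05. Every adjusted p given for a gene is from this test. On simulated data with 200 of 14036 genes changed, the test recovered 58.2% of the changes of 1.5-fold, 82.1% of those of 2-fold and 92.4% of those of 4-fold, with 4 false calls. The changed genes had ESC means of at least 1 on the log2(TPM + 1) scale, and noise was independent between genes. In the data 9397 genes were called, which makes the threshold on p more lenient than in the simulation. These rates therefore check the code and do not describe the real comparison.

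Gene lists (37, covering pluripotency, epiblast, germline, signalling, metabolic, chromatin and reference genes and markers of other cell types) were fixed before the data were examined, as were the tests and the alternatives unless stated otherwise. Each list was tested with camera (limma) against all other tested genes with a preset inter-gene correlation of 0.01, adjusted over the 37 lists, and again with the correlation estimated from the data. The fry test, which asks whether the genes of a list move on balance in 1 direction, called 28 of 37 lists. It does not compare a list with other genes. List symbols missing from the table were matched by 9 older or newer names, such as Cripto for Tdgf1. Some genes are in more than 1 list, such as Klf4, Tfcp2l1 and Gbx2 among both the naive factors and the LIF and STAT3 genes. Results of lists that share genes are therefore not independent.

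Named genes followed a fixed rule. They are the 12 highest and 12 lowest log2 fold changes among called genes with at least 5 TPM in the higher group and no overlap between groups, leaving out predicted genes and pseudogenes, of which the text names a part. Some genes that the rule gives are not reported here. Further named genes are up to 4 called members with the largest change of each main list, or 2 of each secondary list, together with the largest called change in the minority direction. A set of marker and reference genes is named whatever its values, and the most abundant uncalled member of a list can be named.

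The GENCODE M21 mouse annotation (GRCm38) was used by gene identifier for chromosome, gene order, transcript length and GC content. It differs from the build the authors used, so no coordinates are given. It matched 51547 of the 78298 identifiers and 95.1% of the tested genes. X-linked and autosomal genes were compared by median log2 fold change, by camera over 20 chromosomes, and per library by the ratio of median TPM with a two-sided exact permutation test. Unlike the planned ratio, this one left chromosome 8, which stood out in these data, out of the autosomal median. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without mitochondrially encoded genes, sample weights, no variance trend, a replicate block, leaving out each library in turn, a test against a 2-fold change and, for the X chromosome, genes of at least 10 TPM. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used for tables and matplotlib 3.10.9 for plots.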

Results

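Gene expression was measured by poly(A) RNA sequencing in wild-type mouse embryonic stem cells (ESCs), the cultured counterpart of the naive epiblast, and in epiblast-like cells (EpiLCs), a cell state resembling the epiblast after implantation. All cells came from 1 line, which the labels name BVSC clone H18. Each group had 3 libraries, 6 in all, and the deposited table gave 1 TPM value (a transcript's share of a library scaled to 1000000) for each of 78298 genes in each library. Every library summed to 1000000 TPM, so the sequencing depth behind a value is unknown. Between 13610 and 13983 genes reached 1 TPM in a library. The labels call the libraries biological replicates without saying how the cultures were separated, so the p-values measure the spread between these libraries. TPM values below are mean ± SD over n = 3 libraries per group, and fold changes are EpiLC minus ESC on the log2(TPM + 1) scale, which understates changes of weakly expressed genes.

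The comparison of EpiLCs with ESCs asked which genes differ between the naive state and the epiblast-like state. Several transcription factors of naive pluripotency fell steeply in EpiLCs. Klf4 (ENSMUSG00000003032) fell from 105 ± 18.1 to 1.36 ± 0.321 TPM, Tbx3 (ENSMUSG00000018604) from 84.0 ± 7.07 to 0.575 ± 0.0707 TPM and Tfcp2l1 (ENSMUSG00000026380) from 192 ± 5.94 to 4.38 ± 0.741 TPM. The de novo DNA methyltransferases rose, Dnmt3b (ENSMUSG00000027478) from 11.4 ± 0.824 to 426 ± 78.3 TPM and Dnmt3a (ENSMUSG00000020661) from 19.9 ± 1.18 to 419 ± 49.7 TPM. The core factor Pou5f1 (ENSMUSG00000024406), which encodes Oct4, stayed abundant in both states, at 1135 ± 49.1 and 976 ± 67.8 TPM. Of 14036 genes tested with limma, 9397 (66.9%) passed an adjusted p of 0.05, 5062 of them higher and 4335 lower in EpiLCs. Changes of at least 2-fold were found for 1385 higher and 1319 lower genes. With median-of-ratios scaling, 4696 genes were higher and 4663 lower, and at 2-fold the lower genes outnumbered the higher ones (1301 higher and 1411 lower, and 1334 and 1383 with quantile normalization). A limma test against a 2-fold change as the null (treat) called 724 higher and 666 lower genes, and with genes of mean TPM 5 or more only, 820 higher and 846 lower genes passed the 2-fold criterion.

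The genes with the steepest increases included Car4, a membrane-bound carbonic anhydrase, which rose from 0.0596 ± 0.0516 to 127 ± 37.2 TPM (log2 fold change 6.87, SE 0.20, limma adjusted p = 2.6e-07). Gja1, which encodes the gap junction protein connexin 43, rose by 5.74 on the log2 scale, and the Nodal antagonist Lefty1 rose by 5.70. Myc rose by 5.14, the chemokine gene Cxcl12 by 4.97 and the cytoskeletal regulator Crmp1 by 4.97. At the other end, the junctional adhesion molecule gene Jam2 (ENSMUSG00000053062) fell from 261 ± 15.1 to 0.586 ± 0.143 TPM (log2 fold change -7.37, SE 0.09, limma adjusted p = 2.0e-08). The water and glycerol channel gene Aqp3 fell by 6.17 on the log2 scale, and the transcription factor genes Gata2 and Cdx1 fell by 5.91 and 4.97. The rule that picked these genes required that no ESC value overlap an EpiLC value. Over all tested genes, 71.5% met that condition, against 10% given by chance for 3 against 3 libraries.

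**Figure D1:**
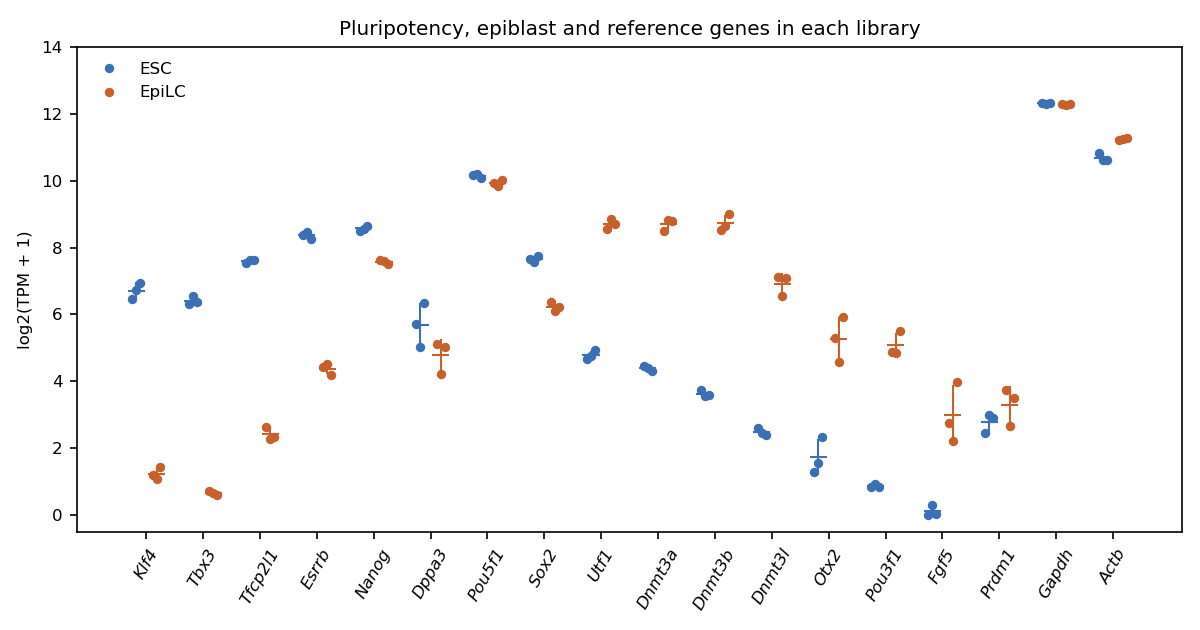
Expression of 18 genes in each library as log2(TPM + 1) on the vertical axis, with ESC libraries in blue and EpiLC libraries in orange (points, single libraries; horizontal lines, group means; vertical lines, SD, n = 3). Klf4, Tbx3, Tfcp2l1 and Esrrb lie far lower in EpiLCs and Dnmt3a, Dnmt3b and Dnmt3l far higher, while the Gapdh values of the groups lie together.

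Of the 17 naive pluripotency factors, 16 fell and 1 rose, with a median log2 fold change of -3.02 (camera adjusted p = 2.7e-07). The adjusted p = 0.295 with an estimated correlation. Esrrb fell from 330.4 ± 23.4 to 19.8 ± 2.26 TPM, Tcl1 by 4.12 and Prdm14 by 4.08 on the log2 scale. Nanog fell less, from 379.7 ± 19.9 to 189 ± 8.71 TPM (SE 0.06 on the log2 scale, limma adjusted p = 3.3e-06). Gbx2 was the member that rose, from 7.63 ± 0.966 to 20.2 ± 3.28 TPM. Dppa3, a germ cell and naive marker, fell from 54.1 ± 24.3 to 27.6 ± 8.59 TPM at a limma adjusted p of 0.049, a call kept in 7 of 17 alternatives and lost without any single library other than ESC replicate 2 (adjusted p between 0.053 and 0.15, and from 0.0017 upward over all alternatives).

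All 18 formative or post-implantation epiblast genes were higher in EpiLCs, with a median log2 fold change of 2.80 (camera adjusted p = 3.9e-07). The adjusted p = 0.295 with an estimated correlation. Besides Dnmt3a and Dnmt3b, the POU factor gene Pou3f1 rose from 0.825 ± 0.0734 to 33.4 ± 9.25 TPM and Fgf15 by 3.68 on the log2 scale. Otx2 (ENSMUSG00000021848), a homeobox gene of the anterior epiblast, rose from 2.47 ± 1.36 to 40.1 ± 18.4 TPM (log2 fold change 3.54, SE 0.37, limma adjusted p = 7.8e-05). Fgf5 (ENSMUSG00000029337), the classical marker of this state, reached 5.74, 3.61 and 14.8 TPM in the EpiLC libraries against at most 0.227 TPM in ESCs (log2 fold change 2.88, SE 0.40, limma adjusted p = 3.9e-04). Among 15 pluripotency factors shared by both states, 11 rose and 3 fell (median 1.09, camera adjusted p = 0.011, and adjusted p = 0.295 with an estimated correlation). Utf1 rose from 26.6 ± 2.59 to 416 ± 40.7 TPM, and L1td1, Lin28a and Lin28b rose by 2.96, 2.69 and 2.66. Sox2 fell from 201 ± 12.2 to 74.5 ± 6.96 TPM and Pou5f1 by 0.22 on the log2 scale (limma adjusted p = 0.012), a call that was lost without the replicate 2 libraries of both groups (log2 fold change -0.15, adjusted p = 0.071, range over alternatives 0.0010 to 0.071), a setting chosen after seeing the data. The cell adhesion gene Cdh1 did not pass the test, at 319 ± 44.8 and 354 ± 27.6 TPM, but passed without ESC replicate 2 (log2 fold change 0.26, adjusted p = 0.016) and with replicate number as a block (adjusted p = 0.025, range over alternatives 0.016 to 0.542). For each list, the number of members called when adjusted over the list alone equalled the number called over all genes, unless another count is given.

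Genes of the DNA methylation machinery moved in both directions. Of 16 genes, 8 rose and 6 fell, with the same counts adjusted over the list alone, and the list as a set did not stand apart from other genes (median 0.23, or 0.056 with a filter at 5 TPM, camera adjusted p = 0.551). The de novo enzymes Dnmt3a and Dnmt3b and their cofactor Dnmt3l (from 4.60 ± 0.405 to 122 ± 26.1 TPM) rose by more than 4 on the log2 scale. Uhrf1, which recruits the maintenance methyltransferase, fell from 453 ± 7.25 to 256 ± 5.59 TPM, and Mbd3 rose by 0.93. The dioxygenase gene Tet1 was at 79.2 ± 6.36 and 82.7 ± 11.3 TPM and did not pass the test.

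**Figure D2:**
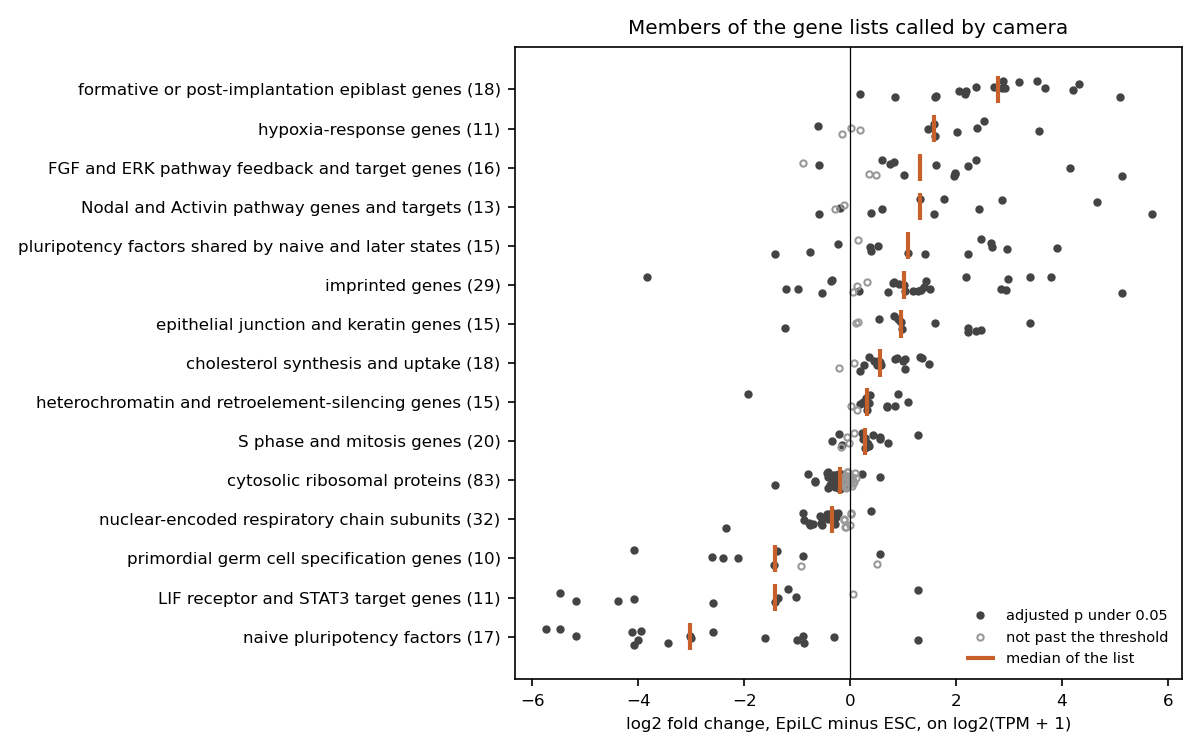
Log2 fold changes (EpiLC minus ESC, horizontal axis, on log2(TPM + 1)) of the tested members of the 15 gene lists called by camera with its preset correlation, with the number of tested members in parentheses (filled points, members past an adjusted p of 0.05; open points, other members; orange bars, list medians). Naive pluripotency factors lie at a median of -3.02 and formative epiblast genes at 2.80.

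Germline genes that carry promoter methylation in somatic cells moved both ways, 10 of 23 higher and 7 lower, also when adjusted over the list alone (median 0.24, or 0.41 without EpiLC replicate 2, camera adjusted p = 0.768). Dazl, an RNA-binding protein gene of germ cells, fell from 41.6 ± 14.7 to 7.78 ± 0.308 TPM, and the tubulin gene Tuba3a, which has a near-identical copy and is therefore uncertain, by 1.73 on the log2 scale. Mael rose by 2.05. Zfp42, which encodes the ESC marker Rex1, fell by 1.62. Of 10 primordial germ cell specification genes, 7 fell and 1 rose (median -1.41, or -0.92 with no TPM filter, camera adjusted p = 0.011, and adjusted p = 0.295 with an estimated correlation). Kit fell by 2.61, Tfap2c by 2.40 and Alpl, the alkaline phosphatase gene, from 331 ± 3.36 to 76.4 ± 15.6 TPM, while Dnd1 rose by 0.57. Prdm1, which encodes Blimp1, was at 5.95 ± 1.30 and 9.28 ± 3.61 TPM and did not pass the test (log2 fold change 0.51, limma adjusted p = 0.138), and it did pass without EpiLC replicate 2 (log2 fold change 0.84, adjusted p = 0.0063, range over alternatives 0.0051 to 0.387). Among 7 tested genes of the 2-cell-like state, many of them near-identical copies whose reads could be split between them, 2 fell over all genes and 1 when adjusted over the list alone (camera adjusted p = 0.744). Zscan4c was at 4.17 ± 0.305 and 2.69 ± 0.0270 TPM, and Eif1ad8 at 1.46 ± 0.540 and 0.725 ± 0.239 TPM, the latter called in 8 of 15 alternatives and lost without ESC replicate 2, EpiLC replicate 1 or EpiLC replicate 3 (adjusted p = 0.060, 0.093 and 0.145) and with a replicate block (adjusted p = 0.082, range over alternatives 0.037 to 0.145).

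Imprinted genes were higher as a group, 20 of 29 rising and 6 falling, also when adjusted over the list alone (median 1.02, camera adjusted p = 0.0042, and adjusted p = 0.295 with an estimated correlation). Peg10, a retrotransposon-derived gene, rose from 2.97 ± 0.290 to 138 ± 9.41 TPM, the noncoding RNA H19 from 1.17 ± 0.382 to 29.6 ± 8.49 TPM and Nnat by 3.39 on the log2 scale. Plagl1, a zinc finger factor gene, fell from 25.8 ± 3.62 to 0.869 ± 0.147 TPM.

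Signalling genes changed in several pathways. FGF and ERK feedback and target genes rose, 12 of 16 higher and 1 lower, or 13 and 1 adjusted over the list alone (median 1.32, camera adjusted p = 9.3e-04, and adjusted p = 0.364 with an estimated correlation). The ERK phosphatase gene Dusp6 rose from 3.96 ± 0.424 to 88.3 ± 13.8 TPM, Etv1 by 2.37 and Spry4 by 2.23, whereas Spry2 fell by 0.58. Of 13 Nodal and Activin genes, 9 rose and 2 fell (median 1.32, camera adjusted p = 0.033, and adjusted p = 0.295 with an estimated correlation). Lefty1 rose from 2.81 ± 0.797 to 198 ± 52.0 TPM and Skil by 2.43 on the log2 scale, and the receptor gene Acvr1b fell by 0.59. LIF receptor and STAT3 target genes fell, 9 of 11 lower and 1 higher (median -1.42, camera adjusted p = 2.4e-04, and adjusted p = 0.295 with an estimated correlation). Socs3, the feedback inhibitor of STAT3, fell from 102 ± 13.4 to 5.02 ± 0.590 TPM and Bcl3 by 4.38 on the log2 scale.

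Canonical Wnt targets did not move together, 5 of 10 rising and 3 falling (camera adjusted p = 0.858), and their median of 0.25 (-0.028 with no TPM filter) and the upward direction of the test differed in sign from their mean of -0.19. Lef1 rose by 3.20 and Nkd2 by 1.65, while Cdx1 fell by 4.97 and the Wnt deacylase gene Notum by 2.65. Of 6 tested BMP targets, 3 rose and 1 fell (camera adjusted p = 0.768), with Smad7 higher by 0.60 while Id4 fell by 1.41.

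Metabolic genes changed in several groups. Nuclear-encoded respiratory chain subunits were lower, 24 of 32 falling and 1 rising, also when adjusted over the list alone (median -0.35, camera adjusted p = 3.3e-06, and adjusted p = 0.385 with an estimated correlation). Cox7a1 fell from 91.1 ± 4.17 to 17.2 ± 3.18 TPM, Cox5a by 0.89 and Cox6a1 by 0.88, and the cytochrome c gene Cycs rose by 0.40. Cholesterol synthesis and uptake genes were higher, 16 of 18 rising and the other 2 not passing the test (median 0.57, camera adjusted p = 1.3e-04, and adjusted p = 0.295 with an estimated correlation), among them Mvd by 1.36 and Lss from 54.1 ± 9.65 to 153 ± 12.6 TPM. Of 20 glycolysis genes, 12 rose and 5 fell (median 0.34, camera adjusted p = 0.406). The glucose transporter gene Slc2a1 rose from 76.9 ± 8.87 to 320.2 ± 27.1 TPM and Pdk1, whose kinase inhibits pyruvate dehydrogenase, by 2.31, while the isoform genes Hk1 and Ldhb fell by 2.35 and 1.95. The threonine and glycine list held 5 higher and 4 lower genes of 12 (camera adjusted p = 0.824), with a median of 0.10 (0.047 with median-of-ratios scaling) and an upward test against a mean of -0.12. Threonine dehydrogenase, Tdh, fell from 281 ± 33.0 to 11.8 ± 0.576 TPM and Amt by 1.18, while Mat2a rose by 2.19 and Gldc by 1.23.

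Hypoxia-response genes rose, 7 of 11 higher and 1 lower (median 1.59, camera adjusted p = 0.039, and adjusted p = 0.510 with an estimated correlation), a call lost without ESC replicate 2 (adjusted p = 0.054) and without a variance trend (adjusted p = 0.051, range over alternatives 0.0024 to 0.054). Egln3, a HIF prolyl hydroxylase gene, rose from 6.54 ± 0.997 to 89.7 ± 21.8 TPM and Bnip3 by 2.53, and Vegfa fell by 0.61. Of 14 p53 targets, 9 fell and 4 rose (camera adjusted p = 0.126, and 0.026 with no TPM filter). The cell cycle inhibitor gene Cdkn1a fell from 178 ± 15.8 to 25.1 ± 1.45 TPM, and Tap1 rose by 1.23. Integrated stress genes split 4 higher and 4 lower of 13 (median 0.03, or -0.019 with median-of-ratios scaling, against a mean of -0.10 and a downward test, camera adjusted p = 0.757), with Chac1 up by 1.86 and Ddit3 down by 1.72. S phase and mitosis genes were higher for 13 of 20 and lower for 3, or 13 and 4 adjusted over the list alone (median 0.29, camera adjusted p = 0.046, and adjusted p = 0.510 with an estimated correlation). That call held in 8 of 17 alternatives and was lost without ESC replicate 2, ESC replicate 3 or EpiLC replicate 2 (adjusted p = 0.057, 0.056 and 0.065) and without both replicate 2 libraries (adjusted p = 0.079). It was also lost with a replicate block (adjusted p = 0.059), under median-of-ratios or quantile scaling (adjusted p = 0.072 and 0.056), with sample weights (adjusted p = 0.053) and without a variance trend (adjusted p = 0.084, range over alternatives 0.0024 to 0.084). The mitotic kinase genes Plk1 and Aurka rose by 1.29 and 0.71, the replication helicase gene Mcm3 fell by 0.35, and Pcna was at 475 ± 15.7 and 500.2 ± 10.7 TPM without passing the test.

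Among 15 heterochromatin and retroelement-silencing genes, 12 rose and 1 fell (median 0.32, camera adjusted p = 0.011, and adjusted p = 0.452 with an estimated correlation), with Ehmt1 higher by 1.10 and Morc1 lower by 1.92. Polycomb genes were higher for 7 of 17 and lower for 5 (camera adjusted p = 0.578), with Phc1 and Jarid2 higher by 1.28 and 0.82 and Eed lower by 0.65. Epithelial junction and keratin genes rose, 12 of 15 higher and 1 lower (median 0.95, camera adjusted p = 0.0016, and adjusted p = 0.364 with an estimated correlation). The epithelial splicing factor gene Esrp1 rose from 3.31 ± 0.911 to 44.0 ± 4.55 TPM and Cgn by 2.46, while Cldn4 fell by 1.22. Of 7 mesenchymal genes, 3 rose and 3 fell (camera adjusted p = 0.789), among them Mmp2 up by 2.04 and the fibronectin gene Fn1 down from 457 ± 72.2 to 74.8 ± 3.28 TPM. Immediate early genes held 2 higher and 5 lower of 12 (camera adjusted p = 0.294), among which Fos fell by 2.92 on the log2 scale, with Junb down by 1.42 and Jund up by 0.57.

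Cytosolic ribosomal protein genes fell by small amounts, 59 of 83 lower and 2 higher, or 60 and 3 adjusted over the list alone (median -0.19, or -0.11 with quantile normalization, camera adjusted p = 2.1e-06, and adjusted p = 0.510 with an estimated correlation). Their share of all TPM was 21.5 ± 0.489% in ESCs and 18.9 ± 0.408% in EpiLCs. Ribosomal protein genes have many near-identical copies, so single values are uncertain. The tissue-restricted paralogs Rpl10l and Rpl39l fell by 1.42 and 0.80, and Rps4l rose by 0.57. Mitochondrially encoded genes were higher for 8 of 13 and lower for 2 (camera adjusted p = 0.194), with mt-Nd4l up by 1.25 and mt-Nd6 down by 1.21. The share of mitochondrially encoded genes in all TPM was 2.66 ± 0.253% in ESCs and 3.39 ± 0.309% in EpiLCs, with at most 2.95% in an ESC library and at least 3.21% in an EpiLC library. The shares of 3 copies of mitochondrial genes listed under other names (Gm28437, Gm28661 and Atp6-ps, chosen after their values were seen) summed to 1.75 ± 0.221% and 2.32 ± 0.112%. Of 6 tested Hox genes, 4 fell and 1 rose (camera adjusted p = 0.082), with Hoxc13 down from 11.4 ± 0.501 to 0.369 ± 0.0537 TPM, Hoxc4 down by 2.73 and Hoxb2 up by 1.37. The Hox set passed without EpiLC replicate 1 or EpiLC replicate 2 (adjusted p = 0.017 and 0.0095) and with no TPM filter (adjusted p = 0.0022, range over alternatives 0.0022 to 0.120). Replication-dependent histone genes, most of which lack a poly(A) tail, gave 4 higher and 4 lower of 32, with a median of 0.03 and a downward test (camera adjusted p = 0.907), with H2bc27 up by 1.44 and H2ac12 down by 0.80.

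Most markers of other cell types were below the filter. Only 5 of 16 primitive endoderm markers were tested, with Dab2 and Col4a1 up by 2.84 and 1.56 and Lama1 and Gata4 down by 2.45 and 1.22 (2 higher and 2 lower, or 3 and 2 adjusted over the list alone, camera adjusted p = 0.858). Of 5 tested trophoblast markers, 3 fell (camera adjusted p = 0.194), namely Plet1 by 1.69, Eomes by 1.04 and Esx1 by 0.82. Primitive streak markers fell for 5 of 6 tested genes and rose for 1 (camera adjusted p = 0.082), with Gsc down from 4.69 ± 1.19 to 0.193 ± 0.0767 TPM and Fgf8 up by 1.75. The mesoderm gene T (ENSMUSG00000062327) was below the filter, at 0.932 ± 0.0723 and 0.356 ± 0.0397 TPM. Of 7 tested neuroectoderm markers, 5 rose and 1 fell (median 1.61, camera adjusted p = 0.194), and the median was 0.062 with no TPM filter. Sox11, Tubb3 and Sox1 rose by 2.18, 2.08 and 2.03, and Hesx1 fell by 3.30. Fibroblast markers, included for feeder cells, were higher for 3 of 5 and lower for 1 (camera adjusted p = 0.464). Tagln rose by 2.49 on the log2 scale, Dcn was listed at 0 in all ESC libraries and reached 1.46, 2.31 and 3.00 TPM in EpiLCs, and Pdgfrb fell by 1.19.

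Of 14 commonly used reference genes, 6 rose and 5 fell, or 6 and 6 adjusted over the list alone, with a median of -0.02 (0.0079 after quantile normalization), a mean of 0.10 and a downward test (camera adjusted p = 0.858). Gapdh (ENSMUSG00000057666) was at 5099 ± 23.0 and 5004 ± 49.7 TPM and did not pass the test (log2 fold change -0.03, and 0.050 after quantile normalization). Actb (ENSMUSG00000029580) rose from 1647 ± 131 to 2444 ± 50.3 TPM, and Tfrc rose by 1.88 on the log2 scale. In all, camera called 15 of 37 lists, some of which share genes, with its preset correlation and 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05. The estimated correlation was -0.0012 for Nodal and Activin genes and -0.023 for imprinted genes, both below the preset 0.01. Their unadjusted camera p still rose, from 0.011 to 0.055 and from 0.0010 to 0.021. A higher estimated correlation therefore does not account for the loss of these 2 calls.

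The X chromosome was compared between the states because X-linked dosage can change as cells leave the naive state. The median log2 fold change of 525 X-linked genes differed from that of the autosomes by -0.000802, while the test of X pointed upward (camera adjusted p = 0.989), and limma's camera called 0 of 20 chromosomes, with 0 at an unadjusted p under 0.05. The difference was -0.12 without ESC replicate 2 and 0.089 without EpiLC replicate 2, and was not called in either case (adjusted p = 0.942 and 0.965). The ratio of the X-linked to the autosomal median TPM, with chromosome 8 left out of the autosomes, was 0.723 ± 0.117 in ESCs and 0.795 ± 0.114 in EpiLCs (n = 3 each, two-sided exact permutation p = 0.5, where the smallest possible p was 0.1). The replicate 2 libraries had the lowest ratios, 0.590 in ESCs and 0.664 in EpiLCs against 0.809 and 0.771 in the other ESC libraries and 0.867 and 0.853 in the other EpiLC libraries, so that EpiLCs had the higher ratio within each replicate number. Xist (ENSMUSG00000086503), the RNA that silences 1 X chromosome in female cells, was below the filter, at 0.0696, 0.0666 and 0.00915 TPM in ESCs and 2.49, 0.321 and 2.72 TPM in EpiLCs. Of 7 tested genes of the X-inactivation centre and its regulators, 5 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.194, and 0.0061 with no TPM filter, range over alternatives 0.0061 to 0.562). Rlim, which encodes an activator of Xist, rose from 35.8 ± 5.16 to 85.7 ± 2.82 TPM and Ftx by 1.08 on the log2 scale, while Spen fell by 0.53.

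**Figure D3:**
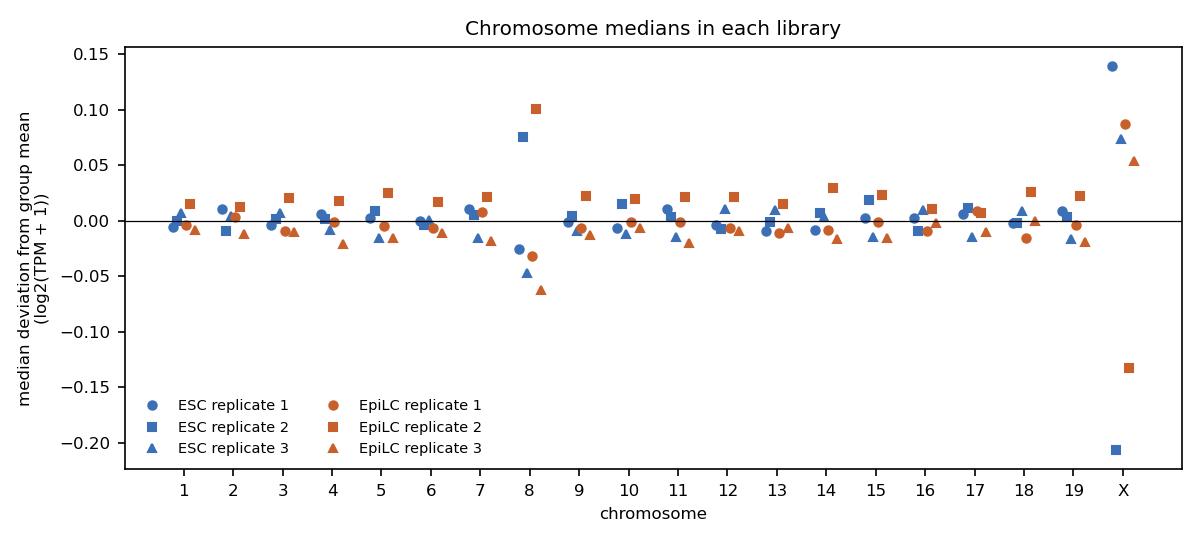
Median deviation of the genes of each chromosome from their group mean, in log2(TPM + 1) (vertical axis), for each library (blue, ESC; orange, EpiLC; circles, squares and triangles, replicates 1, 2 and 3). The squares lie at -0.21 and -0.13 on the X chromosome and at 0.08 and 0.10 on chromosome 8, and within 0.03 of 0 on the other 18 autosomes.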

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

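The setting without both replicate 2 libraries and the paired test of the X ratio were chosen after seeing the data. Counts of changed genes stayed within 1.5 times of 9397 in every setting run, between 8582 and 8961 with 1 library or both replicate 2 libraries left out, 7100 with a filter at 5 TPM and 11031 with no TPM filter, where 10093 and 36675 genes were tested. The counts of genes changed at least 2-fold (1385 higher, 1319 lower) were 820 and 846 with a filter at 5 TPM, where fewer genes were tested, and 724 and 666 in the test against a 2-fold change, a stricter null. They rose to 1709 and 1648 with a pseudocount of 0.1 and to 1556 and 1493 with a pseudocount of 0.5. With an estimated inter-gene correlation, naive factors (median -3.02) and formative genes (2.80) no longer passed (adjusted p = 0.295 for both), and in the other 17 alternatives both did. The X-linked difference from autosomes was not called in any setting with a test. Its sign turned with a pseudocount of 0.5 (0.00074), no filter (0.0071) and median-of-ratios scaling (0.0048), and it ranged from -0.12 to 0.089 with libraries left out, while genes of at least 10 TPM gave -0.073, with no test run. The cause was not tested. For lists that were not called, the direction given by camera turned with no filter for Wnt targets (median -0.028), BMP targets (0.037), mesenchymal (0.24), primitive endoderm (-0.098) and histone genes (0.029), the BMP and histone medians staying positive. For histone genes it also turned with median-of-ratios scaling (median 0.00044), sample weights (0.0072) and some libraries left out (medians from -0.079 to 0.14), and for reference genes with quantile normalization (0.0079). Gapdh turned with quantile normalization (0.0504), and Tet1 ranged from -0.040 to 0.16 with libraries left out. The causes were not tested. Over all lists and named genes together, 614 list values and 2222 gene values kept their direction and side of the threshold, 26 and 18 were no longer past it, and 6 and 5 newly passed. Depth is unknown, so no limit from depth can be given.

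Replicate numbers were checked for pairing. Deviations of same-numbered libraries from their group means correlated at 0.10, 0.14 and 0.065 (Pearson r across genes), not all above 0.1, so the numbers were not taken as pairs. For genes of at least 10 TPM these r were 0.26, 0.21 and 0.060, against -0.23 to -0.0026 for libraries of different numbers. Every library correlated best with the library of its own number. Without X-linked genes the same-numbered r were 0.076, 0.069 and 0.040. The libraries numbered 2 also shared a shift of X-linked and chromosome 8 genes, described below. These 2 libraries therefore shared a feature across groups, and a link between the other same-numbered libraries stays possible. The main fit ignores any such link. A replicate block gave 9612 called genes, 5135 higher and 4477 lower, with 1392 and 1327 at 2-fold, medians of -3.02 for naive and 2.80 for formative genes, and an X-linked difference of -0.000802. Taken by number, the ratio of X-linked to autosomal median TPM (without chromosome 8) was higher in EpiLCs for 3 of 3 numbers, by a mean of 0.0713 (two-sided exact sign-flip permutation p = 0.25, the smallest that 3 pairs allow).

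Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many called genes as the real groups (9397), which was the real one, and the highest of the others gave 2. Each of the other splits mixed both states on both sides, so the difference between states added to the spread and few calls were nearly fixed. The contrast therefore does not estimate the number of false calls. With 10 splits no share under 0.05 can be reached.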

Other observations

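The tests of library scaling for both patterns and of Xist, the gene-name families and the replicate comparison were chosen after the result was seen. Sorting the tested genes by shared symbol stems gave 195 families of at least 8 members, of which camera called 7. RNA helicases with Ddx symbols were higher in EpiLCs (27 of 34 rose and 3 fell, median 0.42, adjusted p = 0.016), as were ubiquitin-related Ube genes (25 of 38 rose and 3 fell, median 0.31, adjusted p = 0.047) and kinesins with Kif symbols (18 of 29 rose and 2 fell, median 0.34, adjusted p = 0.049). The families Cox (17 of 25 fell and 3 rose, median -0.47, adjusted p = 0.018), Ndufb (10 of 13 fell and 1 rose, median -0.38, adjusted p = 0.047), Ndufa (9 of 14 fell and 0 rose, median -0.31, adjusted p = 0.047) and Atp (34 of 65 fell and 10 rose, median -0.24, adjusted p = 0.016) were lower and share members with the respiratory chain list. The Atp family was grouped by that symbol stem alone and has 65 genes, against 32 in the whole respiratory chain list, so most of it lies outside that list. For each of the 7 families, the adjusted p = 0.808 with an estimated correlation.

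In both groups, the library numbered 2 had lower X-linked and higher chromosome 8 expression than the other libraries. Median deviations from the group mean were -0.207 and -0.133 on X and 0.0752 and 0.101 on chromosome 8, and 63.0% of X-linked genes lay below both other replicates in both groups, against 11.5% on the other autosomes and 11.1% by chance. The other 18 autosomes deviated by at most 0.0298, and the share of deviating genes was at least 2.89 times that of these autosomes. Both chromosomes were picked by their medians in these same libraries, so these 2 outcomes were nearly fixed. They therefore do not test scaling, depth or a few strong genes as the cause. X-linked genes were lower and chromosome 8 genes higher, which 1 scaling factor per library cannot give. GC content or length is argued against, since at least 0.803 of each deviation remained after correction. Silencing by Xist stays open, because Xist lay below the filter (mean 0.946 TPM), although it was not the highest of its group in replicate 2, at 0.129 times the lowest other library in EpiLCs and between 0.956 and 7.27 times the others in ESCs. Another hypothesis left open is copy number, with fewer X and more chromosome 8 copies in part of the replicate 2 cells. The medians of 5 blocks of neighbouring genes on each chromosome deviated in the predicted direction in each of the 2 libraries (20 of 20 medians). Both chromosomes already stood out by their medians in these same libraries, so this outcome was nearly fixed. It shows that the shift was spread along each chromosome and cannot tell copy number from other chromosome-wide causes. The design names no factor that sets replicate 2 apart, and DNA was not measured here. The camera tests of replicate 2 against 1 passed with the preset correlation (adjusted p = 5.4e-13 for chromosome 8 and 1.0e-45 for X) and not with an estimated correlation (adjusted p = 0.556 and 0.618).

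Ribosomal protein and nuclear respiratory chain genes both had lower medians in EpiLCs, by -0.233 and -0.393 relative to all tested genes with a known transcript length. Of 83 ribosomal protein genes 59 were lower and 2 higher, and of 32 respiratory chain genes 24 were lower and 1 higher. Both lists are short genes, with median transcripts of 1049 and 1232 nt against 3075 nt for all, so length bias was weighed. After its correction the list closest to the median of all genes, that of ribosomal protein genes, still lay at -0.146 (bootstrap SE 0.0194). Lengths were those of the longest annotated transcript, which need not be the expressed transcript. The correction therefore cannot tell how much of the shift length accounts for. GC content (-0.202 after a separate correction with the same transcripts) is argued against as the whole cause, with the same limit. A factor per library shifts all genes alike, so median-of-ratios scaling could hardly move a list relative to all genes. Its result (-0.237) is therefore no test of that cause. Quantile normalization left a ribosomal median of -0.114 (camera adjusted p = 0.0016). Without rescaling, neither list passed with an estimated correlation (adjusted p = 0.510 for ribosomal and 0.385 for respiratory chain genes). A lower expression of both groups in the epiblast-like state remains a hypothesis that these libraries alone cannot test further, and a difference in RNA quality was not tested, although mitochondrially encoded genes held a higher share of TPM in EpiLCs (3.39% against 2.66%).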
